A study of Homo sapiens with 28 samples.

How the data were processed

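ChIP-seq of the histone marks H3K27ac, H3K4me1, H3K4me3, H3K36me3 and H3K27me3, with a mock IgG control, was compared between SCC25 and HGEP, with 2 biological replicates of each cell line per target. SCC25 is an established oral squamous cell carcinoma line, and HGEP are primary gingival epithelial cells of a single donor. The 24 peak lists of these libraries were used. The 4 input samples had no peak list here and were not analysed. Per the labels' protocols, fixation was in 1% formaldehyde (10 min), and chromatin was sheared to between 100 and 300 bp. SCC25 was grown with 10% serum and 400 ng/ml hydrocortisone and HGEP in another medium, so cell line, donor, malignancy and medium cannot be separated.

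Per the submitters' processing notes, FastQC 0.10.0, Bowtie 1.1.1, SAMtools 0.1.19 and Picard were used with hg19 (GRCh37). The peak caller, its threshold and its control are not given in the sources used here. The authors deposited 1 broad peak list per library, so replicates were not pooled. Each deposited row gives a peak's position, a fold (a ratio over background) and a p-value and q-value as −log10. These are the authors' values for peaks within 1 list and were used only to filter or rank peaks in that list. Read depth is unknown, so no interval that needs it is given. The lists held between 42954 and 872716 peaks on chromosomes 1 to 22 and X, the only chromosomes used.

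The design fixed before the data were examined kept peaks with a −log10 q of at least 2. A reproducible region was a merged run of kept peaks holding a peak of each replicate, and it counted as belonging to 1 line only when no kept peak of either replicate of the other line overlapped it by 1 bp. Enhancer clusters were H3K27ac peaks stitched within 12.5 kb, ranked by the sum of fold times width, above the point of slope 1 of the scaled rank curve. With 2 libraries against 2, an exact permutation test cannot go below p = 0.333, and the design set no test on these counts. Shares per library were left without a test by choice. Fisher p-values over regions were computed for the H3K27me3 overlaps but are not reported, because regions are not replicates. Each count was set beside the counts from the other splits of the same 4 libraries into pairs. The 10 clusters of highest mean rank per line were to be named.

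That filter turned out to have little relation to replicate overlap. A second selection, the 20000 widest peaks of each library, was therefore added after the overlaps within and between lines had been seen. Clusters of this selection were ranked by bases under peaks. It is an alternative to the design, and its values are named as such throughout. Comparisons of H3K27ac regions with other marks used chromosomes 1 to 22, a restriction made after the values with chromosome X had been seen. Random placement moved each region to a uniform position on its chromosome 100 times. It did not leave out sequence where no peak can be called, which can lower the random shares. Shares of regions have 95% Wilson intervals, which treat regions as independent although neighbours are not.

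Planned promoter, gene body and gene list results needed hg19 gene models, which were not used here, so no region was assigned to a gene and the KLF4 locus was not examined. The gene table at hand follows another assembly and lent no coordinates. Band names came from the hg19 table of circlize 0.4.16. Calculations used Python 3.11.15 with NumPy 2.4.6 and SciPy 1.17.1, and figures matplotlib 3.10.9. The interval code was tested on simulated H3K27ac lists with 200 planted regions per line: 89.5% of the SCC25 and 92% of the HGEP regions were recovered, and 44 and 34 other regions were called. The simulation copied a single list into every library, moved the edges and dropped a small share of peaks. These values follow largely from that share, so they check the code and not the recovery in these data. Coordinates are 1-based.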

Results

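Genome-wide maps of 5 histone marks were compared between SCC25, a line from an oral squamous cell carcinoma, and HGEP, primary gingival epithelial cells. The series title names super-enhancers and the transcription factor KLF4 in head and neck carcinoma, and the design compares the chromatin of the 2 cell types. Each mark had 2 libraries per line. The marks are known for active promoters and enhancers (H3K27ac), enhancers (H3K4me1), promoters (H3K4me3), transcribed gene bodies (H3K36me3) and Polycomb repression (H3K27me3). The H3K27ac lists of SCC25 held 184287 and 312767 peaks and those of HGEP 378591 and 132358. At the designed filter, a −log10 q of at least 2, the SCC25 IgG lists kept 360 and 197 peaks and the HGEP IgG lists 15 and 0.

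At the designed filter, H3K27ac marked 23721 reproducible regions in SCC25, of which 11012 were SCC25-only, and 15904 in HGEP, of which 5359 were HGEP-only. H3K4me3 gave 14948 SCC25-only and 2742 HGEP-only regions, H3K4me1 3307 and 2189, H3K36me3 4215 and 2880, and H3K27me3 179 and 1575. In no mark did both lines exceed every mixed pair, made of 1 SCC25 and 1 HGEP library. For H3K27ac the mixed pairs had between 3008 and 9812 regions of their own, for H3K4me3 they reached 3894 and for H3K36me3 3388, and the highest mixed value of each was below the SCC25 count and above the HGEP count. For H3K4me1 they reached 6196, above both counts. For H3K27me3 they reached 275, above the SCC25 count and below the HGEP count. The Jaccard index, shared bases over the union, was 0.194 between SCC25 H3K27ac replicates and 0.163 between HGEP replicates, against 0.114 to 0.206 across lines. Both replicate pairs exceeded every pair across lines in 1 of the 5 marks, H3K27me3.

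**Figure D1:**
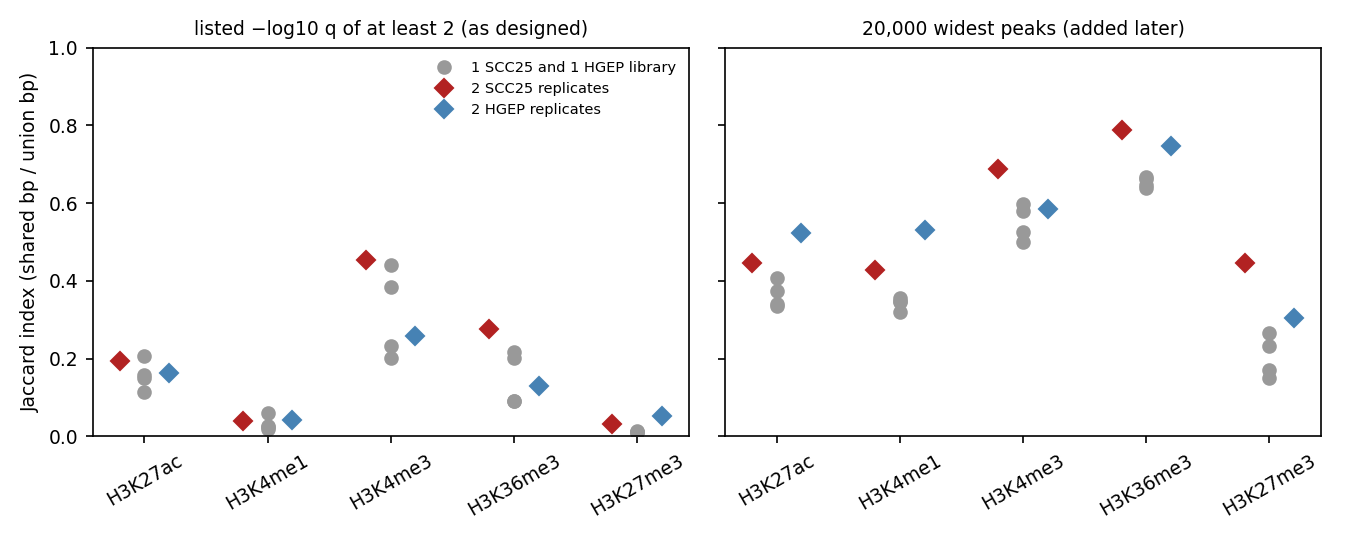
Jaccard index of peak lists for each mark, under the designed filter (left) and for the 20000 widest peaks (right). Diamonds are replicate pairs and grey points the pairs of 1 SCC25 and 1 HGEP library. Both diamonds lie above all grey points in 1 mark on the left and 4 on the right.

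The listed q had little relation to whether a peak recurred. Over the 20 libraries of the marks, a median 39.2% of midpoints of the 20% of peaks with the lowest −log10 q lay under a peak of the other replicate, against 45.6% for the 20% with the highest −log10 q. By width the medians were 18.3% for the narrowest 20% and 84.1% for the widest 20%. Among the 20000 widest peaks, an alternative chosen after these overlaps were seen, the Jaccard index of H3K27ac was 0.447 between SCC25 and 0.522 between HGEP replicates, against 0.335 to 0.408 across lines. For H3K36me3 it was 0.789 and 0.746 within lines, against 0.639 to 0.666 across. H3K4me3 was the exception, with 0.584 between HGEP replicates and up to 0.598 across lines.

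By width, 2736 of 12532 reproducible SCC25 H3K27ac regions were SCC25-only and 2797 of 13896 HGEP regions HGEP-only, with at most 641 in mixed pairs. H3K4me1 gave 2752 SCC25-only and 3561 HGEP-only regions against at most 707. H3K4me3 gave 1929 and 1332 against at most 451, H3K36me3 1824 and 1383 against at most 267, and H3K27me3 4896 and 3661 against at most 999. The same was seen at 10000 and 40000 peaks, with both lines above every mixed pair in each mark. The 2 selections picked different places. Of the 11012 SCC25-only H3K27ac regions of the designed filter, 308 overlapped an SCC25-only region by width and 205 an HGEP-only one. A region absent from the widest peaks of the other line still mostly held some peak there, since 85 SCC25-only and 131 HGEP-only H3K27ac regions overlapped no deposited peak of the other line.

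**Figure D2:**
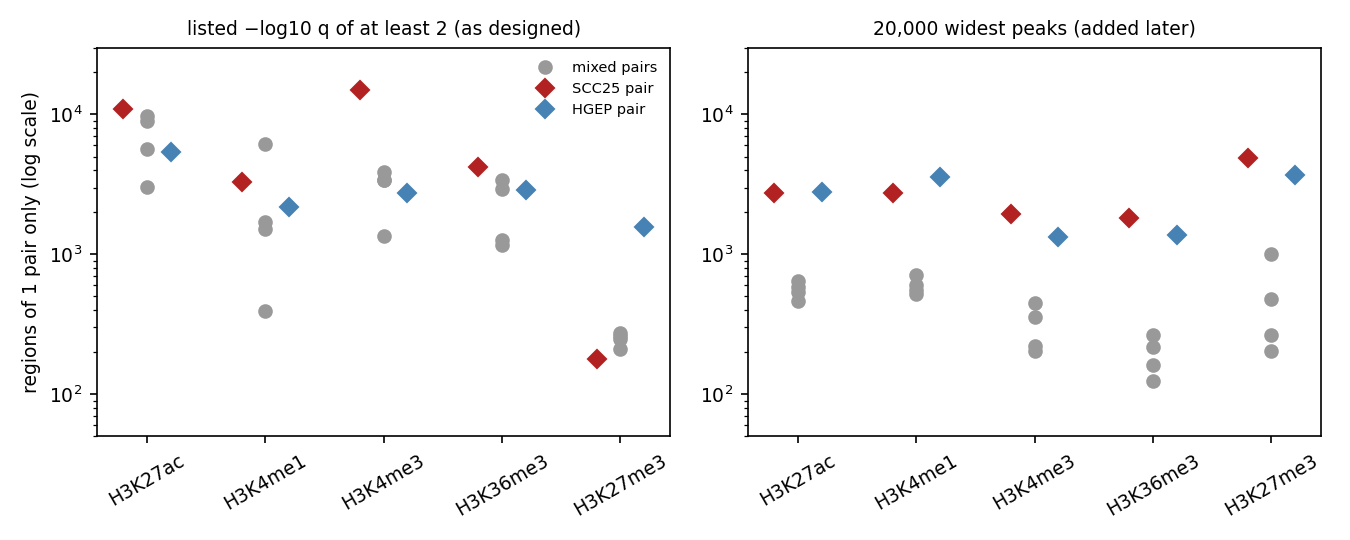
Regions found in 1 pair of libraries and not in the other pair, on a log axis, under the designed filter (left) and for the 20000 widest peaks (right). Diamonds are the pairs of 1 line and grey points the mixed pairs. On the right, each diamond lies above each grey point of its mark.

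H3K27ac regions of the 2 lines differed in the marks they carried in the other line. By width on chromosomes 1 to 22, 55.7% ± 0.76 (SD, n = 2) of the 2683 SCC25-only regions held H3K4me1 in SCC25 and 31.5% ± 1.55 (SD, n = 2) in HGEP. Of the 2703 HGEP-only regions, 60.8% ± 1.15 (SD, n = 2) held it in HGEP and 16.5% ± 1.07 (SD, n = 2) in SCC25. H3K36me3 lay on 32.1% of SCC25-only regions in SCC25 and on 21.6% in HGEP, and on 32.2% and 32.6% of HGEP-only regions. In SCC25, IgG peaks overlapped 15.8% ± 6.91 (SD, n = 2) of the SCC25-only regions and 16.3% ± 8.91 (SD, n = 2) of the shared ones, but 6.83% ± 0.759 (SD, n = 2) of the HGEP-only ones. HGEP IgG peaks overlapped 5.46% ± 2.93 (SD, n = 2) of SCC25-only and 7.03% ± 2.83 (SD, n = 2) of HGEP-only regions.

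Of the 2683 SCC25-only H3K27ac regions, 248 overlapped a reproducible HGEP H3K27me3 region, 9.24% (Wilson interval 8.20% to 10.4%), against 87 of 9623 shared regions, 0.904%. In the reverse comparison, 45 of 2703 HGEP-only regions, 1.66% (1.25% to 2.22%), overlapped SCC25 H3K27me3, against 33 of 10902 shared regions, 0.303%. Randomly placed regions gave 7.56% and 9.01%, with highest values of 8.72% and 10.5%, so the SCC25-only share lay just above the random range and the HGEP-only share below its mean. Because placement can give random shares that are too low, the small SCC25 margin is no evidence of an excess. For H3K4me1 the shares were 24.6% of SCC25-only and 1.81% of HGEP-only regions (random means 7.30% and 9.18%), for H3K4me3 17.4% and 6.89% (6.14% and 8.18%) and for H3K36me3 5.89% and 2.67% (8.15% and 10.8%). Shared regions of SCC25 and HGEP gave 5.24% and 2.13% for H3K4me1, 10.8% and 7.27% for H3K4me3 and 0.588% and 0.461% for H3K36me3. Many SCC25-only regions over the mark held it in SCC25 too. No kept SCC25 H3K27me3 peak lay on 284 of 668 for H3K4me1 and 104 of 328 for H3K4me3. Of the HGEP-only regions over SCC25 H3K27me3, 39 of 63 and 14 of 89 held none in HGEP. At the designed filter, 0.496% of SCC25-only and 0.0378% of HGEP-only H3K27ac regions overlapped the mark of the other line, against random means of 0.460% and 0.0661%.

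**Figure D3:**
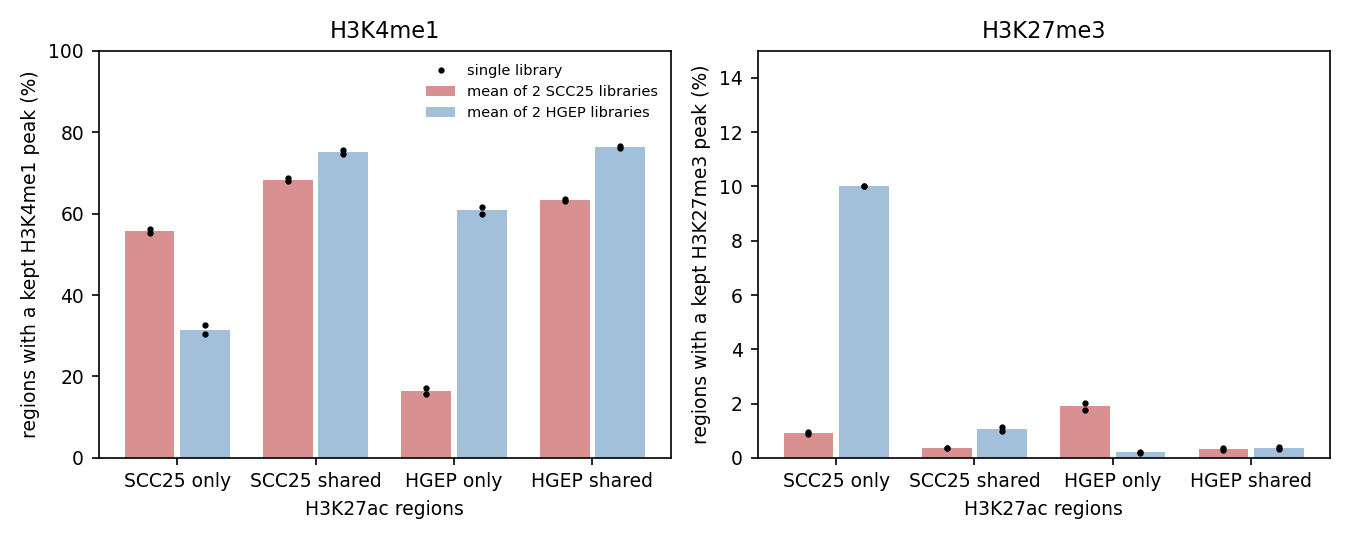
Percent of H3K27ac regions (20000 widest peaks, chromosomes 1 to 22) with a kept H3K4me1 peak (left) or H3K27me3 peak (right). Bars are means of 2 libraries and points single libraries. HGEP H3K27me3 lay on 10.0% of SCC25-only regions and SCC25 H3K27me3 on 1.91% of HGEP-only regions.

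Of the 248 SCC25-only H3K27ac regions over HGEP H3K27me3, 225 held no kept SCC25 H3K27me3 peak, and examples were taken from these. Low H3K27me3 in SCC25 and low H3K27ac in HGEP were thus favoured by the choice. The longest of them, singled out after its values were seen, lay on chromosome 12, 54365103 to 54396239 (hg19, band 12q13.13). Deposited H3K27ac peaks covered 97.8% and 90.1% of it in the SCC25 libraries and 0.575% and 0% in the HGEP libraries. H3K36me3 covered 55.9% and 53.9% in SCC25 and 0.482% and 0% in HGEP, and H3K27me3 covered 100% in both HGEP libraries and 0% and 9.53% in SCC25. At chromosome 20, 57113201 to 57134371 (20q13.32), H3K27ac covered 99.2% and 78.5% in SCC25 against 3.63% and 0% in HGEP. A 60.7 kb SCC25-only H3K36me3 region, 57075531 to 57136265, spanned that stretch. In the reverse comparison, 44 of the 45 HGEP-only regions held no kept HGEP H3K27me3 peak, and the example was chosen from these in the same way. The longest of them, chromosome 11, 61593614 to 61606443 (11q12.2), had H3K27ac over 96.8% and 91.4% in HGEP and 10.0% and 10.1% in SCC25, where H3K27me3 covered 100% and 91.3%.

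The designed ranking gave 703 reproducible enhancer clusters in SCC25, 288 of them SCC25-only, and 466 in HGEP, 112 of them HGEP-only. Mixed pairs of libraries gave 56 to 174 clusters of their own. The highest ranked SCC25-only clusters lay on chromosome 16, 11011891 to 11258464 (16p13.13), chromosome 19, 43914637 to 44332299 (19q13.31), chromosome 17, 3400713 to 3628666 (17p13.2), chromosome 6, 43394448 to 43752950 (6p21.1) and chromosome 12, 53397906 to 53500219 (12q13.13). At the first of these, deposited H3K27ac peaks covered 57.0% ± 12.9 (SD, n = 2) in SCC25 and 30.2% ± 10.9 (SD, n = 2) in HGEP. The next ranks were on chromosome 20, 62150860 to 62374679, chromosome 8, 145512664 to 145778536, chromosome 22, 43002265 to 43148874, chromosome 11, 57488298 to 57609745, and chromosome 22, 28056000 to 28212128.

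The highest ranked HGEP-only clusters lay on chromosome 9, 27330061 to 27541268 (9p21.2), chromosome 3, 145769350 to 145899922 (3q24), chromosome 12, 76498479 to 76705384 (12q21.2), chromosome 20, 1355773 to 1487418 (20p13) and chromosome 15, 64670629 to 65013481 (15q22.31). H3K27ac covered 54.7% ± 7.42 (SD, n = 2) of the 3q24 cluster in HGEP and 19.4% ± 7.19 (SD, n = 2) in SCC25. At 9p21.2 it covered 62.4% and 60.3%, a difference smaller than the replicate spread. The next ranks were on chromosome 21, 17101647 to 17199302, chromosome 5, 86408769 to 86734348, chromosome 2, 227582306 to 227678764, chromosome 9, 14095328 to 14204161, and chromosome 3, 124691200 to 124782971. Both libraries of the own line had more covered bases than both of the other in 6 of the 10 SCC25-only and 6 of the 10 HGEP-only clusters. Over all designed clusters this held in 163 of 288 SCC25-only ones, with the opposite in 7, and in 53 of 112 HGEP-only ones, with the opposite in 5. Peak width is part of the ranking, so these counts are no independent support.

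By width and covered bases, 173 of 542 SCC25 clusters were SCC25-only and 137 of 572 HGEP clusters HGEP-only, against 12 to 31 in mixed pairs. The highest ranked were chromosome 12, 50897294 to 51043613 (12q13.12) in SCC25, at 83.2% ± 0.519 (SD, n = 2) against 56.6% ± 10.9 in HGEP, and chromosome 3, 185372699 to 185492041 (3q27.2) in HGEP, at 81.8% ± 8.45 (SD, n = 2) against 55.7% ± 5.98 in SCC25. Of the 288 designed SCC25-only clusters 36 overlapped one of these, and of the 112 HGEP-only clusters 12. By width, 2 clusters of each line overlapped no kept H3K27ac peak of the other.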

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

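The tests of the listed q values and the IgG overlap were chosen after the results were seen. In 3 of the 4 mock IgG lists, more peaks lay over H3K27ac regions than in any random placement. Of the 20000 widest IgG peaks, 15.3% in SCC25 replicate 1 lay over reproducible H3K27ac regions of the line, against at most 6.33% in 100 random placements. In SCC25 replicate 2 the value was 6.50% against at most 6.43%. Because placement can give random shares that are too low, this small margin is no evidence of an excess. In HGEP replicate 2 the value was 8.91% against at most 4.59%, while HGEP replicate 1 had 2.63% against a random mean of 5.23%.

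Replicate overlap hardly rose with the listed q. One explanation, that replicates share few peaks, is argued against by the widest 20% of peaks, of which at least 50% of midpoints lay under a peak of the other replicate in 18 of 20 libraries. Another, that columns 7 to 9 do not belong to the peak of their row, may account for it, but stays open. The gain in midpoints hit by q over that by width reached 0.268, above the bound of 0.25 set for every library, with a median of 0.0969. Neighbouring peaks had related q values (Spearman's rho across peaks, which are not independent, 0.449 to 0.905), while q and width of a peak were only weakly related, positively in all 20 libraries (0.0139 to 0.120). No biological explanation was tested.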

How the results depend on the processing

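The settings with 20000, 10000 or 40000 widest peaks, with the other line judged by every deposited peak, and with clusters ranked by bases were chosen after seeing the data. The designed counts changed by over 1.5 times under many settings, and the cause was not tested except where named. Counts are given as SCC25-only and HGEP-only, and only those that moved by more than 1.5 times. With all deposited peaks: H3K27ac 20222 and 13925, H3K4me1 60381 and 17688, H3K36me3 6807 and 12381, H3K27me3 37905 and 12277, clusters 167 and 176. At a −log10 q of at least 5: H3K27ac 2064 (HGEP), H3K4me1 260 and 43, H3K36me3 919 and 207, H3K27me3 27 and 419, clusters 47 (HGEP). With the same number of peaks per library: H3K27ac 4031 (SCC25), H3K4me1 511 and 800, H3K4me3 4385 (SCC25), H3K36me3 1581 (HGEP), H3K27me3 337 (HGEP), clusters 101 (SCC25). With 50% of the length needed to count as shared: H3K27ac 8138 (HGEP), H3K4me3 4815 (HGEP), clusters 480 and 185. Stitching within 5 kb gave 175 HGEP clusters, and 6 and 3 clusters had no kept H3K27ac peak of the other line. Ranking clusters by bases moved no count past that bound. Leaving out peaks that overlap IgG peaks did not either, but with 360, 197, 15 and 0 IgG peaks kept it could hardly remove any, so IgG background was not tested by it.

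By width, the counts that moved were, at 20000 peaks, H3K27ac 2736 and 2797, H3K4me1 3561 (HGEP), H3K4me3 1929 and 1332, H3K36me3 1824 and 1383, H3K27me3 4896 and 3661, clusters 173 (SCC25), at 10000 H3K27ac 1490 and 1552, H3K4me1 1453 (SCC25), H3K4me3 812 and 720, H3K36me3 907 and 731, H3K27me3 2599 (SCC25), clusters 85 (SCC25) and at 40000 H3K27ac 4878 (SCC25), H3K4me1 5307 and 6864, H3K4me3 6360 (SCC25), H3K27me3 8211 and 6127. With the other line judged by every deposited peak: H3K27ac 4026 and 2063, H3K4me1 1295 and 347, H3K36me3 906 and 990, H3K27me3 46 and 181. Marks whose replicate pairs both exceeded every pair across lines numbered 1 as designed, 2 with all deposited peaks, 2 with the same number of peaks per library, 4 at 20000, 5 at 10000 and 4 at 40000 widest peaks. Leaving out each library in turn gave these ranges: SCC25 H3K27ac 15223 to 77792, HGEP H3K27ac 7044 to 96265, SCC25 H3K4me1 3458 to 67819, HGEP H3K4me1 2359 to 44777, SCC25 H3K4me3 19240 to 54446, HGEP H3K4me3 4085 to 122958, SCC25 H3K36me3 4941 to 28976, HGEP H3K36me3 3860 to 41033, SCC25 H3K27me3 204 to 8463, HGEP H3K27me3 1619 to 25780, SCC25 clusters 383 to 1127, HGEP clusters 162 to 1029. By construction, a line with 1 library left needs no second replicate, which raises its count. The share of H3K27ac regions over H3K27me3 of the other line was higher for SCC25-only regions in 11 of 13 settings. The exceptions, 0.454% against 0.734% and 0.444% against 0.919%, left out SCC25 replicate 1 and 2. The shares themselves moved with the selection: 28.2% against 17.8% with all deposited peaks, and 9.24% against 1.66% at 20000, 5.04% against 0.656% at 10000 and 16.3% against 4.14% at 40000 widest peaks, with random placement run only as designed and at 20000.

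No paired analysis was possible because the results come from overlap and no test, and replicate numbers do not tie the lines together. Of same-numbered libraries, 77.2% and 86.1% of SCC25 H3K27ac peaks had no overlap in HGEP at the designed filter. Promoter, gene body and gene list results and settings around transcript starts were not run without hg19 gene models. Read depth is unknown, so its effect on these counts was not tested.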

Other observations

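The comparisons of this part, and its tests except that on IgG background, were chosen after results were seen. They use the 20000 widest peaks or the deposited lists, except for values named as at the designed filter, where leaving out a library was a planned setting. SCC25-only and HGEP-only regions leaned to opposite marks in 2 of the 4 bands to which HOX gene clusters, regulators of body patterning, are assigned. It was not determined whether any region covers a HOX gene. In 17q21.32 (HOXB), 13 H3K27ac regions were SCC25-only and 0 HGEP-only, H3K4me3 gave 13 and 2 and H3K36me3 7 and 1, while H3K27me3 gave 0 and 11. In 12q13.13 (HOXC), H3K27ac gave 11 and 2 and H3K36me3 13 and 0, while H3K27me3 gave 2 and 15. In 7p15.2 (HOXA), H3K27ac gave 7 and 2, H3K4me3 4 and 0, H3K36me3 1 and 0 and H3K27me3 9 and 2. Band counts can hide single places. At an SCC25-only H3K4me3 region there, chromosome 7, 27149893 to 27156386, H3K27ac covered 100% in both SCC25 and 0% in both HGEP libraries. H3K27me3 covered 0% and 100% of it. That region was taken from those over HGEP H3K27me3 without a kept SCC25 H3K27me3 peak, which favoured these H3K27me3 values. In 2q31.1 (HOXD), H3K27ac gave 10 and 14 and H3K27me3 14 and 15. Such leans were not limited to these bands. In 10q22.1, H3K27ac gave 16 and 7 and H3K27me3 1 and 29, and in 2q14.2 they gave 14 and 6 and 0 and 32. These are counts without a test, and no rate over all bands was computed.

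In 118 stretches, 23.9 Mb in all, windows of 20 kb were chosen for at most 1 peak in the 10 SCC25 histone mark lists and at least 8 in those of HGEP, with IgG held out, after a first form that counted IgG in the choice had given 8 stretches with SCC25 IgG peaks at 2.35% of their mean autosomal density, a value that the choice itself fixed. Fewer peaks listed in SCC25 is argued against by mark lists with 1.12 times as many autosomal peaks as those of HGEP. Over all stretches together, closed chromatin and complete or partial loss of the DNA in SCC25 cannot be told apart. With IgG held out of the choice, the SCC25 IgG density was 57.3% (57.3% for both tests). The libraries lay on both sides of the bound of 50%, at 34.7% and 78.4%. The rule that both must meet a bound was set after these values were seen. The stretches were uneven. In 107 of them, of 17.2 Mb, the density of both libraries together was 58.4% to 117% of the mean, and in 1 it was 33.7%. By library, these 108 stretches lay at 47.8% in SCC25 IgG replicate 1, below the bound of 50%, and at 107% in replicate 2. Complete loss would leave almost no IgG peaks, so these values argue against it as the cause of the whole pattern. Partial loss in these stretches stays open. The other 10, of 6.58 Mb, lay at no more than 5.99%. The longest stretches, 2900 kb in 4q35.2 and 2360 kb in 21q22.2, were among them, at 1.61% and 2.97%. The lengths of these 2 came from the mark lists alone, with IgG held out. They held 26 and 39 SCC25 IgG peaks, against 987 and 781 HGEP IgG peaks. So few SCC25 IgG peaks are what loss of the DNA would give at these 2 stretches. The 10 as a group were set apart by their IgG density, so the group cannot test loss. The input samples were not analysed, and loss of the DNA stays open for these 10. Of the 131 HGEP-only H3K27ac regions without any SCC25 peak, 38 lay in the stretches, 31 of them in those 10, and over the 5 marks it was 170 of 854, with 140 in the 10. The choice of windows with few SCC25 and many HGEP peaks itself favoured this overlap.

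SCC25-only H3K27ac regions lay over HGEP H3K27me3 more often than the reverse (9.24% against 1.66%). Beside random placement, the HGEP-only share lay far below its mean of 9.01%, and the SCC25-only share was near its own, 7.56%. Beside the shared H3K27ac regions, at 0.904% for SCC25 and 0.303% for HGEP, each share was higher. Which of these baselines is the better one was not tested. By width, more of the genome under H3K27me3 in HGEP is argued against by random placement, whose HGEP over SCC25 ratio was 0.838. IgG background at the regions stays open as a cause of this difference by width. Only regions under the widest SCC25 IgG peaks were left out, and HGEP IgG peaks were not used. Those SCC25 IgG peaks had a Jaccard index of 0.0234 between replicates, so they can miss background. Of the 1912 SCC25-only regions left, 7.69% lay over the mark, against 9.24% of all SCC25-only and 1.66% of HGEP-only regions. The difference thus remained, but the regions left out lay over the mark more often than those left. The share of 7.69% is no longer above the random placements of all SCC25-only regions. With the designed filter, more of the genome under H3K27me3 in HGEP stays open as the cause of the direction. Reproducible H3K27me3 regions of that filter covered 9.52 Mb in HGEP and 1.45 Mb in SCC25. Its random means were 0.460% for SCC25-only and 0.0661% for HGEP-only H3K27ac regions, with highest values of 0.618% and 0.170%. The observed shares, 0.496% and 0.0378%, lay below those highest values, and random placement gave the same direction. At the designed filter the direction turned without SCC25 replicate 1 (0.454% against 0.734%) or 2 (0.444% against 0.919%) and held without HGEP replicate 1 (2.64% against 0.0153%) or 2 (2.34% against 0.0672%), but a line with 1 library left needs no reproducible H3K27me3 region, which by construction raises the overlap with it. With 1 carcinoma line and 1 primary cell type in different media, a difference of cell type, donor or culture was not tested and stays open.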
